A study of Mus musculus with 103 samples.

How the data were processed

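Liver RNA of C57BL6/J mice was measured on 103 Affymetrix mouse arrays, 1 per sample. Per the labels, the mice were young or old, had been fed a normal or a calorie-restricted diet for 25 weeks, were kept in 12 h light and 12 h dark, and were sampled every 4 h; RNA was extracted with TRIzol, amplified with WTA2 for 17 cycles from 25 ng and labelled with biotin. The deposited values are log2 intensities of 21261 probe sets, made by the authors with RMA per the submitters' processing notes; the RMA version is not given in the sources used here. Values ran from -1.28 to 14.2. Raw intensities and detection calls were not used here, so signal over background could not be measured array by array.

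The groups were taken from the labels: age, diet and time of day, with 24 combinations of 3 to 6 arrays. Where the age in weeks went against the group of the title, the title was followed: a young restricted array at ZT16 (replicate 5) carried an age of 88 weeks, and a young normal-diet array at ZT4 (replicate 4) an age of 23 weeks. The labels number the replicates but do not say that they came from separate animals, so the p-values measure the spread between these samples. No 2 arrays held identical values; the correlation of pairs of arrays lay between 0.9392 and 0.9962. The deposited values carried no difference by labelled sex: 823 of the 21261 probe sets (3.87%, where chance gives 5%) had an unadjusted p under 0.05 for sex and 0 passed after adjustment, and Xist, the transcript that silences an X chromosome in females, averaged 4.38 (SD 0.65, n = 55) in labelled females and 4.26 (SD 0.32, n = 48) in labelled males. No source used here records such an adjustment. Comparisons of age and diet are within-sex averages; whether such an adjustment also moved them is open. No difference between the sexes as such is reported.

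Probe sets were named from the platform annotation, with symbols updated through their gene IDs to those of the GRCm38.p6 assembly. Of the probe sets, 15869 had 1 gene symbol, 225 several and 5167 none; 153 of those with a symbol had a gene ID not matched there. Each gene was represented by its probe set with the highest mean, which gave 15716 genes, and the 3929 genes with the lowest means (25%, below a log2 mean of 4.131) were left out, so that 11787 were tested. For 130 of these genes 132 other probe sets existed; their median correlation with the chosen probe set was 0.251, and 29 correlated below 0.

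Linear models were fitted with limma 3.58.1 in R 4.3.3 (with version 1.17.8 of the data.table package), with all arrays in each fit so that the groups shared 1 estimate of the spread. For levels the model had a mean for each of the 24 combinations and a term for sex, and each contrast was the mean of the differences at the 6 times (eBayes with trend; 78 residual degrees of freedom, median residual SD 0.155). For rhythms it had a mean, a cosine and a sine term with a period of 24 h for each age and diet group and a term for sex, and moderated F tests were made of the cosine and sine terms of a group or of their differences between groups. Amplitude is the height of the fitted curve above its mean on the log2 scale. Errors are standard errors on the log2 scale unless called SD, fold changes are 2 to the power of the log2 difference, and p-values are two-sided and adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05.

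Before the data were examined, 34 testable gene lists were fixed: pathways of liver metabolism, stress and immunity, protein complexes, and markers of hepatocytes and of other cell types. They were tested with camera at a preset correlation of 0.01, with camera at a correlation estimated from the data and with fry, each adjusted over the 34 lists of a comparison; only lists with at least 3 measured genes were tested. The genes to be named were fixed by a rule at the same stage: up to 12 genes in each direction with the largest change among those past the threshold and with the same sign at 5 or more of the 6 times, leaving out predicted genes and genes of the sex chromosomes, all measured clock genes, and the 10 genes with the largest amplitude or difference in rhythm. Members of the fixed lists are named as examples.

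The shift in the time of the clock was tested on the 13 clock genes rhythmic in every group, as the median difference of their peak times in a fit without a sex term, by a permutation test with 100000 resamples. Overlaps of calls are set beside the number that independent lists would share, the product of the counts divided by the genes tested. For pairs of comparisons that share arrays, correlations and covariances were set beside 100 simulations of unchanged groups. Counts were also taken in 100 groupings of the arrays, the real one included, in which labels were exchanged within times of day (for rhythm, times within a group). The fits of level and rhythm, a rank test of rhythm and camera were tried on simulated data with known answers, and the other tests were not. The simulated noise was normal and independent between genes, with the same spread in every group and no outlying array. For age on the normal diet 87% of genes with a log2 change of 0.3 and 99% with 0.6 were recovered. For the diet effect in old mice 90% and 99% were, and for the interaction 70% and 98%. For rhythm in young mice on the normal diet 89% of genes with an amplitude of 0.3 were recovered. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.

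The alternatives tried were other filters on dim genes, quantile normalization, median centring, the mean of a gene's probe sets, array weights, a model without sex, each sex alone, only the groups compared, equal numbers of arrays, other tests of rhythm, the arrays with contradictory ages left out, arrays standing over 5 median absolute deviations apart left out, each array or replicate number left out, and the replicate number as a term. Runs without 4 young arrays with outlying sex-linked transcripts and without the 2 arrays with the highest neutrophil values were chosen after seeing the data. Probe sets without a single gene name were left out of the report.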

Results

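Transcripts were measured in livers of C57BL6/J mice that differed in age and diet and were sampled around the clock. Young and old mice of both sexes had been fed a normal diet or a calorie-restricted diet for 25 weeks. Livers were taken every 4 h across a cycle of 12 h light and 12 h dark, from zeitgeber time (ZT, hours after lights on) 0 to 20. On the normal diet there were 25 arrays from young mice (13 female, 12 male, median age 52 weeks) and 22 from old mice (12 female, 10 male, median 88 weeks). Under restriction there were 32 from young mice (18 female, 14 male, median 51 weeks) and 24 from old mice (12 female, 12 male, median 88 weeks). Each group had 3 to 6 arrays per time of day. Array medians lay between 5.06 and 5.22 on the log2 scale. The number of arrays limited the precision of the comparisons. After removal of the 3929 genes with the lowest mean signal, 11787 genes were tested.

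The comparison of old with young mice on the normal diet asked which liver transcripts changed with age, averaged over the 6 times of day. Cd163, the scavenger receptor by which macrophages clear haemoglobin-haptoglobin complexes, fell 2.38-fold in old mice (log2 change -1.25, SE 0.20; 22 old and 25 young arrays; adjusted p = 4.97e-05). Ociad2 fell 1.79-fold (log2 change -0.84, SE 0.13; adjusted p = 4.97e-05) and Mogat1, an acyltransferase of triglyceride synthesis, 1.55-fold (SE 0.16; adjusted p = 0.0115). Noct, the rhythmically expressed phosphatase nocturnin, rose 1.64-fold (SE 0.11; adjusted p = 4.97e-05). Each of these 4 genes moved the same way at 6 of 6 times of day and passed without the arrays that were doubted and in females alone. With only the groups compared in the fit, Mogat1 missed the threshold (adjusted p = 0.0761), as it did in males alone (adjusted p = 0.217).

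Hes7, a transcriptional repressor, had the largest rise (1.92-fold, SE 0.28; 5 of 6 times), and several of the other largest rises were those of immune cell transcripts. Clec7a, the myeloid receptor dectin-1, rose 1.77-fold (SE 0.16; 6 of 6 times), the calprotectin subunit S100a9 1.61-fold (SE 0.16; 6 of 6), the immunoglobulin joining chain Jchain 1.88-fold (SE 0.23; 5 of 6) and the light chain Igk-V21 1.72-fold (SE 0.17; 6 of 6). Pla2g7, which hydrolyses platelet-activating factor, rose 1.60-fold, the lipoprotein lipase Lpl 1.56-fold and lactoferrin (Ltf) 1.55-fold. The gelatinase Mmp9 rose 1.51-fold, Ms4a4b 1.51-fold and Tmem268 1.5-fold. Among the largest decreases were 3 acyl-CoA thioesterases: Acot1 fell 1.80-fold (SE 0.17; 6 of 6 times), Acot3 1.66-fold (SE 0.23; 5 of 6) and Acot2 1.56-fold (SE 0.15; 6 of 6). The peroxisomal thiolase Acaa1a fell 1.45-fold, the inducible chaperone Hspa1b 1.74-fold and the male-biased cytochrome Cyp2d9 1.56-fold. The sulfotransferase Sult2a8 fell 1.44-fold, the water channel Aqp4 1.46-fold and Hectd2 1.58-fold. In all, 594 genes passed, 290 higher and 304 lower, and of these only Cd163 changed more than 2-fold. The balance of directions depended on the scaling of the arrays: 267 of 531 genes that passed were higher after quantile normalization, and 242 of 805 with each array centred on its median. At an unadjusted p under 0.05 there were 2428 genes, where chance gives 589.

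Of 12 lists that camera called for age on the normal diet, 5 lists of immune cells and interferon response were higher, and 2 lists of fat oxidation and respiration were lower. None of the 12 kept its call with an estimated correlation (adjusted p from 0.157 to 0.458). The other 5 are given after these. Of 12 T and NK cell transcripts, 5 rose (10 adjusted over the list alone), among them Nkg7 (log2 change 0.52, SE 0.11) and Cd3e (0.47, SE 0.12). Of 11 Kupffer cell and macrophage transcripts, 5 rose (8 adjusted over the list alone), among them the complement subunit C1qa (0.50, SE 0.14) and Cd5l (0.46, SE 0.14), while the macrophage gene Cd163, which is not in that list, fell. Rises were also found for 3 of 10 MHC class II transcripts (5 adjusted over the list alone; H2-Eb1 0.43, SE 0.13) and for 3 of 3 neutrophil transcripts (3 adjusted over the list alone; S100a9, Ltf and the peptide Camp). Of 16 interferon-response transcripts, 3 rose (7 adjusted over the list alone; Oasl2 0.47, SE 0.12). Of 19 targets of PPAR-alpha and genes of fatty acid oxidation, 9 fell (14 adjusted over the list alone), including the receptor gene Ppara itself (-0.33, SE 0.078), the peroxisomal enzyme Ehhadh (-0.39, SE 0.12) and Cyp4a10 (-0.42, SE 0.11). Of 85 transcripts of oxidative phosphorylation, 19 fell (30 adjusted over the list alone), each by little, as did Ndufa6 (-0.16, SE 0.041). The 7 hepatocyte markers held no gene past the threshold in either direction, with a median of 0.01. The B and plasma cell list was not called (1 of 8 rose, Jchain; 1 adjusted over the list alone; camera adjusted p = 0.0714).

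All of these 7 lists passed the camera test at its preset correlation, with adjusted p from 8.06e-05 for the neutrophil list to 9.90e-14 for oxidative phosphorylation, and all 7 passed the fry test (adjusted p from 0.00105 to 0.0469). With an estimated correlation, adjusted p = 0.157 for T and NK cells, neutrophils and PPAR-alpha targets, adjusted p = 0.23 for MHC class II, interferon response and oxidative phosphorylation, and adjusted p = 0.362 for macrophages. Acetyl-CoA metabolism was also lower (2 of 13 fell, Acot12 and Pdha1; adjusted over the list alone, 1 rose and 5 fell; camera adjusted p = 0.0046, fry adjusted p = 0.00615, and adjusted p = 0.23 with an estimated correlation). A further 4 lists were called by camera only, and each had an adjusted p = 0.458 with an estimated correlation. Cholesterol synthesis (1 of 17 rose, Srebf2) and acute phase (0 of 14 passed) were higher. The 2 others were lower, bile acid synthesis and transport (1 of 16 fell, Abcg5) and xenobiotic metabolism (2 of 20 fell, Gsta4 and Gstm1).

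The array of an old male at ZT16 (replicate 2) had a neutrophil list mean of 9.59 on the log2 scale, where the next array of its group had 6.19, and an acute phase list mean of 11.36 against 10.25. It was the only male array of its group, so every fit of males alone rested on it for old normal-diet mice at ZT16. Without it, 204 genes passed for age on the normal diet. Among the lists, the genes that passed then numbered 5 of 85 for oxidative phosphorylation, 3 of 19 for PPAR-alpha targets, 2 of 12 for T and NK cells, 2 of 3 for neutrophils, 1 of 16 for interferon response and 0 for macrophages and MHC class II. Without 4 young arrays with outlying sex-linked transcripts, 157 genes passed, and the same lists had 2, 3, 2, 1, 0, 0 and 0. Hes7, Ltf, Mmp9, Hspa1b, Acot3, Hectd2, Cyp2d9 and Sult2a8 missed the threshold without the old male array, and Jchain and Igk-V21 as well without the 4 young arrays. The count also moved by over 1.5 times without the old normal-diet arrays ZT20 replicate 3 (214), ZT12 replicate 4 (295), ZT4 replicate 3 (382) or ZT8 replicate 2 (393) or the young normal-diet array ZT20 replicate 3 (390). It was 174 with only the groups compared, where S100a9 and Acaa1a also missed the threshold, and 54, 70 and 252 without the arrays of replicate number 3, 4 or 1. It was 12 in females alone and 1721 in males alone.

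Old and young mice were compared in the same way under caloric restriction. Noct again rose with age, 1.78-fold (log2 change 0.83, SE 0.11; 24 old and 32 young arrays; adjusted p = 9.74e-08; 6 of 6 times), as did Jchain, 1.85-fold (SE 0.21; adjusted p = 0.00794; 6 of 6), and the light chain Iglv1, 1.74-fold (SE 0.15; adjusted p = 0.000521; 6 of 6). Lcn2, the siderophore-binding acute phase protein lipocalin 2, rose 1.88-fold (SE 0.23; adjusted p = 0.0105; 6 of 6). Ociad2 fell 1.67-fold (SE 0.12; adjusted p = 0.000105; 6 of 6) and Me1, the malic enzyme that supplies NADPH for fatty acid synthesis, 1.46-fold (SE 0.13; adjusted p = 0.00827; 6 of 6). Smaller rises were found for Lpl (1.56-fold), Serpinb1a (1.56-fold), Igk-V21 (1.52-fold), Pf4 (1.49-fold) and S100a9 (1.49-fold), and for Csprs (1.47-fold; adjusted p = 1.28e-07), Ms4a6d (1.43-fold) and the plasma glutathione peroxidase Gpx3 (1.42-fold). Slc25a30 fell 1.68-fold, Sult2a8 1.61-fold, Acot1 1.42-fold, the sulfotransferase Sult5a1 1.40-fold, the steroid dehydrogenase Hsd17b6 1.40-fold and the kinetochore gene Spc25 1.40-fold. AY074887 fell 1.40-fold, Keg1 1.39-fold, Gpx6 1.39-fold and the major urinary protein gene Mup3 1.39-fold.

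In all, 911 genes passed for age under restriction, 346 higher and 565 lower, none of them by more than 2-fold. After quantile normalization 390 of 862 genes that passed were higher, and with each array centred on its median 280 of 1143. Xenobiotic enzymes were among those that fell: Cyp3a11 fell by 0.37 on the log2 scale (SE 0.071), Cyp1a2 by 0.44 (SE 0.13) and Sult5a1 by 0.49 (SE 0.085). The xenobiotic list of 20 was not called (4 fell; camera adjusted p = 0.51), and its median of 0.02 and mean of -0.03 differed in sign. Of 10 NRF2 targets, the quinone reductase Nqo1 and the transporter Abcc4 rose, and that list was not called either (camera adjusted p = 0.0939). Camera called 14 lists, and none kept its call with an estimated correlation (adjusted p from 0.472 to 0.554). B and plasma cells were higher (2 of 8 rose, Jchain and Cd79b; 3 adjusted over the list alone; camera adjusted p = 0.00299, fry adjusted p = 0.0118, and adjusted p = 0.472 with an estimated correlation). This was the only list of the 14 that fry also called. Higher at the preset correlation were acute phase (4 of 14 rose, Lcn2, Apcs, Fgl1 and Itih4; 5 adjusted over the list alone), cytosolic ribosome (6 of 58 rose and 1 fell; 12 and 1 adjusted over the list alone) and interferon response (2 of 16 rose, Gbp2 and Psmb9). So were cell cycle (1 of 10 rose, Pcna; 5 adjusted over the list alone), neutrophils (1 of 3 rose, S100a9; 2 adjusted over the list alone), T and NK cells (0 of 12 passed) and macrophages (0 of 11 passed). Lower were lipogenesis (5 of 17 fell, among them Me1, Gpam and Fads2; 5 adjusted over the list alone), PPAR-alpha targets (4 of 19 fell, Ppara and Acot1 among them; 6 adjusted over the list alone) and oxidative phosphorylation (4 of 85 fell), which turned in males alone (median 0.0168, and -0.0992 in females). Also lower were bile acid synthesis and transport (2 of 16 fell, Baat and Abcb4), male-biased liver genes (2 of 14 fell, Mup3 and Nudt7; 3 adjusted over the list alone) and the proteasome (1 of 31 fell). With an estimated correlation each of these had an adjusted p = 0.472, except macrophages (adjusted p = 0.553) and the proteasome (adjusted p = 0.554). The count of genes was 311 in females alone and 3 in males alone. It was 43, 271 and 540 without the arrays of replicate number 3, 2 or 5. It was 546 without the old restricted array ZT4 replicate 3 and 570 without the old restricted array ZT0 replicate 3.

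The age changes on the 2 diets were then set side by side. Of the genes that passed, 63 were higher with age on both diets, Noct, Jchain, Lpl and S100a9 among them, where independent lists would share 8.51. A further 74 were lower on both, Ociad2 and Acot1 among them, against 14.6, and 1 went in opposite directions, against 22.8. Across all genes, which are not independent replicates, the log2 changes with age on the normal diet and under restriction had a Pearson r of 0.578, and these comparisons shared no arrays. Whether the effect of age depended on diet was tested directly, and 2 genes passed, although under several alternatives given below limma called none. Syce2, a component of the meiotic synaptonemal complex, had an interaction of 0.24 (SE 0.048; adjusted p = 0.0198; 6 of 6 times), with a diet effect of -0.01 in young and 0.23 in old mice. The predicted gene Gm10037, which was named after its values were seen, had an interaction of -0.26 (SE 0.049; adjusted p = 0.0126; 6 of 6 times), with diet effects of 0.11 and -0.15. For the interaction 1109 genes had an unadjusted p under 0.05. Cd163 and Lcn2, for example, passed for age on 1 diet only, and neither passed the interaction (adjusted p = 0.28 and 0.722). Camera at the preset correlation called 8 lists for the interaction, none of which kept its call with an estimated correlation (adjusted p = 0.755 for each), and no member gene passed over all genes. The interaction was higher for PPAR-alpha targets, NRF2 targets, oxidative phosphorylation and cytosolic ribosome and lower for cholesterol synthesis, male-biased liver genes, T and NK cells and MHC class II. In females alone the direction turned for cholesterol synthesis, PPAR-alpha targets and oxidative phosphorylation (adjusted p = 0.0744, 0.669 and 0.257). Fry called none of them. In males alone, the old normal-diet group at ZT16 held only the outlying male array. Limma called 0 genes for the interaction without the 4 young arrays with outlying sex-linked transcripts (785 at an unadjusted p under 0.05) and in females alone (891), where in males alone it called 513 (2036). It also called 0 without the arrays of replicate number 1 (903 at an unadjusted p under 0.05) or 4 (933). The count of genes was 4 without the old arrays ZT16 replicate 4 (normal diet) or ZT0 replicate 3 (restricted) and 6 without the young restricted array ZT0 replicate 1 or the old restricted array ZT20 replicate 1.

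**Figure D1:**
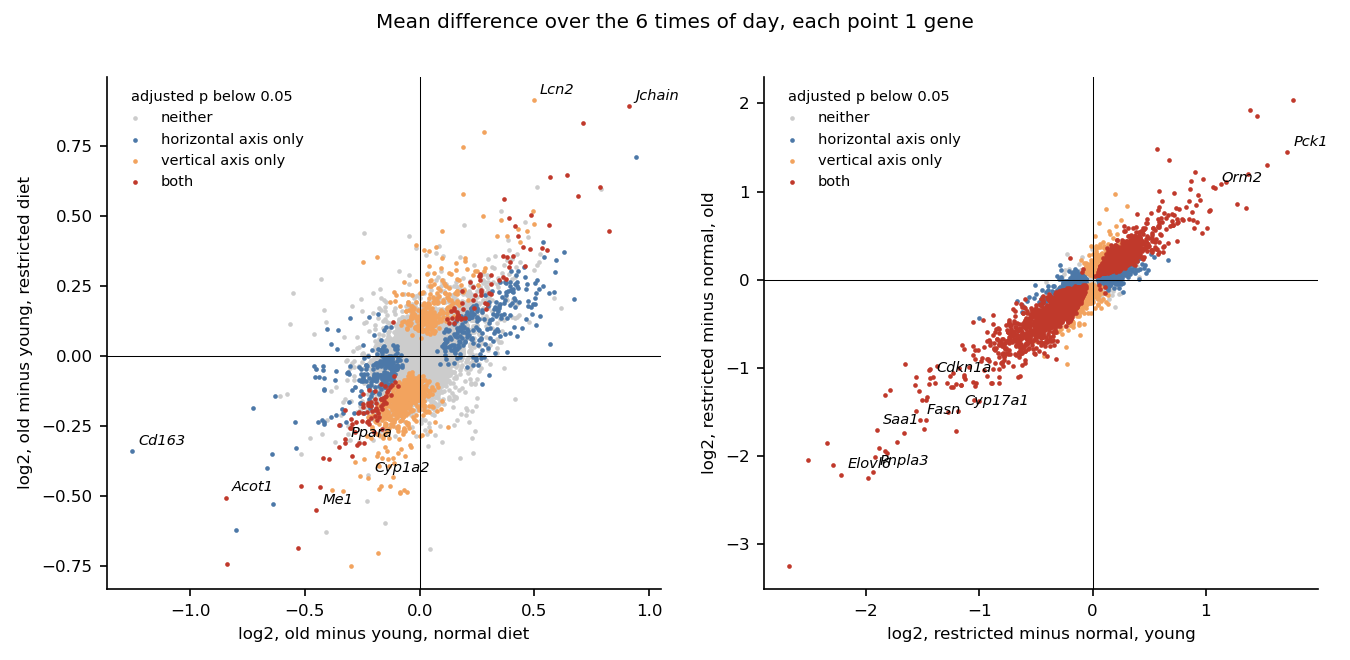
Log2 difference of each of 11787 genes, averaged over 6 times of day, for age on the normal diet against age under restriction (left) and for diet in young against diet in old mice (right), where colours mark genes with an adjusted p under 0.05 on either or both axes. The diet effects lie close to a line (Pearson r 0.912) and reach -2.68 and -3.25 for Serpina12, while the age effects are smaller and scatter more (r 0.578).

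Caloric restriction was compared with the normal diet in young and in old mice. Serpina12, which encodes the adipokine vaspin, had the largest decrease at both ages. It fell 6.39-fold in young mice (log2 change -2.68, SE 0.18; 32 restricted and 25 normal-diet arrays; adjusted p = 3.13e-22) and 9.50-fold in old mice (-3.25, SE 0.20; 24 and 22 arrays; adjusted p = 7.99e-24). The fatty acid elongase Elovl6 fell 4.65-fold in young and 4.63-fold in old mice (adjusted p = 2.86e-21 and 2.07e-18). Pck1, the gene of the gluconeogenic enzyme PEPCK, rose 3.28-fold in young (SE 0.14; adjusted p = 2.92e-17) and 2.73-fold in old mice (SE 0.16; adjusted p = 5.80e-12), and Igfbp2, an IGF-binding protein, 2.58-fold and 2.29-fold. These genes, and the others with the largest diet effects, moved the same way at 6 of 6 times of day.

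Further decreases in young and old mice, in that order, were found for the lipid droplet protein Cidea (5.70-fold and 4.12-fold), the acyltransferase Mogat1 (5.07-fold and 3.61-fold), Rarres1 (4.88-fold and 4.28-fold), the bile acid transporter Slc10a2 (3.95-fold and 4.77-fold) and the lipase Pnpla3 (3.83-fold and 4.53-fold). Me1 fell 3.78-fold and 4.05-fold, the fatty acid binding protein Fabp5 3.68-fold and 3.75-fold and the deiodinase Dio1 3.56-fold and 3.86-fold. The acute phase protein Saa1 fell 3.75-fold and Osbpl3 3.57-fold in young mice, and Adgrv1 fell 3.91-fold and Tcim 3.58-fold in old mice. Rises were found for the organic anion transporter Slc22a26 (3.40-fold and 4.11-fold), the glutathione transferase Gsta2 (2.61-fold and 3.80-fold) and Pcp4l1 (2.73-fold and 3.64-fold). The adropin gene Enho rose 2.91-fold and 2.46-fold, and the prostaglandin transporter Slco2a1 2.26-fold and 2.15-fold. Socs2, Gpx6, Avpr1a, Orm2 and Slco1a4 rose between 2.09-fold and 2.56-fold in young mice, and Cyp2b13, Cyp2b9, Cyp2c37 and Fbxo21 between 2.17-fold and 2.57-fold in old mice. Cd163 rose 2.80-fold in old mice (SE 0.20; adjusted p = 5.05e-09), the reverse of its change with age on the normal diet, although both comparisons used the same old normal-diet arrays. In young mice 5152 genes passed (2401 higher, 2751 lower) and in old mice 4993 (2155 higher, 2838 lower). Which direction held the majority depended on the scaling of the arrays. After quantile normalization 3162 of 5516 genes were higher in young and 3067 of 5353 in old mice, and with each array centred on its median 2970 of 5459 and 2787 of 5265. As deposited, 1422 were higher at both ages, against 439 by independence, 2148 were lower at both, against 662, and 7 went in opposite directions, against 1080.

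Among the gene lists, all 17 measured genes of lipogenesis fell at both ages (17 adjusted over the list alone at each age). Among them, fatty acid synthase Fasn fell by 1.52 in young (SE 0.12) and by 1.59 in old mice (SE 0.13) on the log2 scale, and Thrsp by 1.66 and 1.74. Of 10 p53 targets and senescence genes, 8 fell in young mice (9 adjusted over the list alone) and 10 in old mice (10 adjusted over the list alone). Among them, the cell cycle inhibitor Cdkn1a fell by 1.43 (SE 0.16) and 1.12 (SE 0.18), Ccng1 by 0.72 and 0.61, and Btg2 by 0.65 and 0.88. These were the only lists that kept their camera call with an estimated correlation. With it, adjusted p = 0.00772 for lipogenesis and 0.0126 for p53 targets in young mice, and 0.00647 and 0.0127 in old mice. The urea cycle was higher, with 8 of 8 genes that rose in young and 6 of 8 in old mice, the same counts adjusted over the list alone. Cps1, its entry enzyme, rose by 0.23 and 0.17 (adjusted p = 0.124 in young and adjusted p = 0.283 in old mice with an estimated correlation).

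Several lists of immune and stromal transcripts had members that fell under restriction, and none of these lists kept a camera call with an estimated correlation. Of 16 interferon-response genes, 12 fell in young (13 adjusted over the list alone) and 14 in old mice (14 adjusted over the list alone). Among them, the chemokine Cxcl9 fell by 1.12 and 1.13 on the log2 scale (adjusted p = 0.579 in young and adjusted p = 0.378 in old mice with an estimated correlation). Of 11 stellate cell and fibrosis genes, 7 fell in young and 6 in old mice, with the same counts adjusted over the list alone. Collagen Col1a1 fell by 0.84 and 0.67 and Lrat, which esterifies retinol, by 0.73 and 0.85 (adjusted p = 0.562 and adjusted p = 0.283 with an estimated correlation). In old mice 7 of 10 MHC class II genes fell (7 adjusted over the list alone; H2-Eb1 by 0.95, SE 0.13; camera adjusted p = 0.00279, and adjusted p = 0.378 with an estimated correlation). So did 6 of 12 T and NK cell genes (7 adjusted over the list alone; Nkg7 by 0.49; 0.0194, and adjusted p = 0.528 with an estimated correlation). In the macrophage list 8 of 11 fell and Marco rose by 0.80 in old mice (8 and 1 adjusted over the list alone; C1qa fell by 0.69, SE 0.14; camera adjusted p = 0.0233, and adjusted p = 0.598 with an estimated correlation). In young mice 6 of the 11 macrophage genes, 6 of the 10 MHC class II genes and 2 of the 12 T and NK cell genes fell. These lists missed the camera threshold (adjusted p = 0.158, 0.0729 and 0.421). Of 7 hepatocyte markers 3 rose in young and 4 in old mice, with medians of 0.02 and 0.04.

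Male-biased liver genes were lower at both ages (9 of 14 fell in young and 10 in old mice, with the same counts adjusted over the list alone). Among them, Elovl3 fell by 1.28 and 1.5 on the log2 scale (adjusted p = 0.579 and adjusted p = 0.283 with an estimated correlation). Oxidative phosphorylation was higher, with 36 of 85 genes that rose and 8 that fell in young mice (39 and 9 adjusted over the list alone). In old mice 36 rose and 4 fell (36 and 4 adjusted over the list alone; adjusted p = 0.704 and adjusted p = 0.47 with an estimated correlation). The cytosolic ribosome was higher too. Of its 58 genes, 33 rose and 4 fell in young mice (36 and 4 adjusted over the list alone). In old mice 39 rose and 3 fell (40 and 3 adjusted over the list alone; adjusted p = 0.579 and adjusted p = 0.324 with an estimated correlation). In the xenobiotic list, which was called higher, 10 of 20 genes rose and 1 fell in young mice (10 and 2 adjusted over the list alone) and 9 rose and 4 fell in old mice (9 and 4 adjusted over the list alone). Cyp1a2 rose by 0.88 and 0.67 (adjusted p = 0.579 and adjusted p = 0.283 with an estimated correlation). Acetyl-CoA metabolism was called lower in young mice (7 of 13 fell and 1 rose, the same adjusted over the list alone; camera adjusted p = 0.0137, and adjusted p = 0.396 with an estimated correlation). In old mice 5 fell and 1 rose (camera adjusted p = 0.0666). Fry called every list named here as changed for diet by camera. The count of genes was 2531 in young males alone and 2036 in old females alone, each less than the count of both sexes by over 1.5 times.

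**Figure D2:**
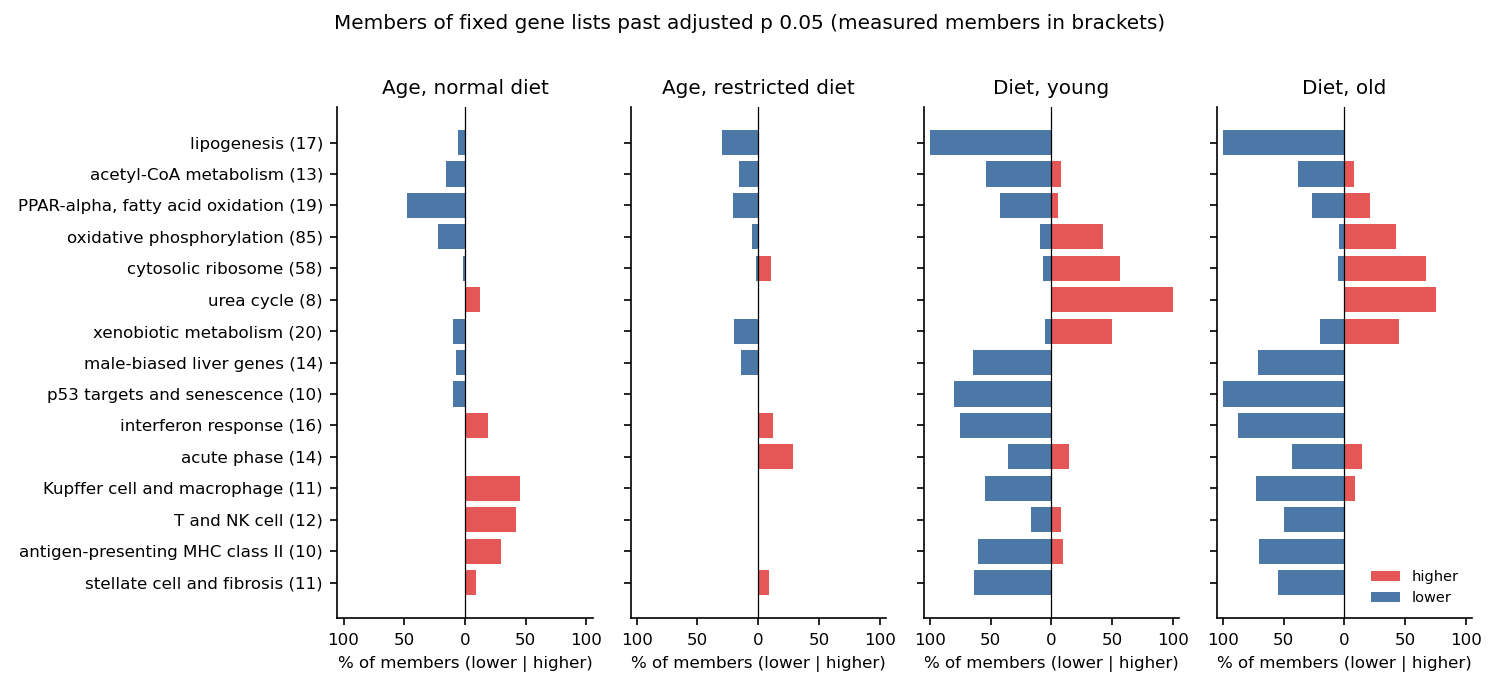
Percent of the measured members of 15 gene lists that were lower (left of 0) or higher (right of 0) at an adjusted p under 0.05 over all genes, for age on each diet and for caloric restriction at each age; the number of measured members stands in brackets. Restriction lowered all 17 genes of lipogenesis at both ages, and on the normal diet age raised 5 of 12 T and NK cell genes and lowered 9 of 19 PPAR-alpha targets.

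Daily rhythms were fitted as 24 h cosine curves in each group. Sphk2, a sphingosine kinase, had the largest amplitude in every group, with a peak-to-trough ratio of 13.1-fold in young and 13.6-fold in old mice on the normal diet and of 34.5-fold in young and 29.7-fold in old restricted mice. The next largest included the deubiquitinase Usp2 (12.7-fold, 12.2-fold, 16.6-fold and 16.6-fold in the same order), the mitotic kinase Wee1 (9.71-fold, 9.05-fold, 16.4-fold and 18-fold) and the clock gene Npas2 (8.9-fold, 10.4-fold, 14.2-fold and 15.9-fold). On the normal diet they also included Lcn2 (5.80-fold) and Cdkn1a (6.11-fold) in young mice and Acot3 (7.35-fold) and Ppp1r3g (6.45-fold), a glycogen-targeting subunit of protein phosphatase, in old mice. At both ages they included the uridine phosphorylase Upp2 (5.56-fold and 7.45-fold). Under restriction they included Cdkn1a (17.1-fold in young and 12.9-fold in old mice), the manganese exporter Slc30a10 (15.8-fold and 19.5-fold), the tight junction gene Cldn1 (14.1-fold and 15.8-fold) and Hspa1b (11.8-fold and 12.7-fold). By the cosine test 3696 genes were rhythmic in young and 3450 in old mice on the normal diet, and 5806 in young and 5098 in old restricted mice. Young and old mice shared 2080 rhythmic genes on the normal diet, against 1082 by independence, and 4135 under restriction, against 2511. A rank test of rhythm called 2420 in young and 1464 in old mice on the normal diet, where the cosine test had 3696 and 3450. With 3 arrays per time in each group, 2506 genes were rhythmic in young and 2774 in old mice on the normal diet, and 3635 in young and 4351 in old restricted mice. In this 1 selection, the arrays of replicate numbers up to 3, there were more in old than in young mice on either diet, the reverse of the order with all arrays. Other selections of equal size were not tried. With 1 replicate number left out, the counts on the normal diet ran from 2218 to 3677 in young and from 1614 to 3467 in old mice. Whether the order depends on the number of arrays is therefore open. In females alone 1203, 404, 3652 and 2520 genes were rhythmic in the same order of groups, and in males alone 802, 2610, 3131 and 3102.

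Core clock genes cycled in all 4 groups. Of 15 measured clock genes, 13 were rhythmic in every group. The others were Rora, which was rhythmic in none, and Bhlhe40, which was rhythmic under restriction. Under restriction the amplitudes of these 13 genes were larger, by a median ratio of 1.51 in young mice and 1.24 in old mice, and larger in 12 of 13 genes at each age. Per2, a repressor of the clock, had an amplitude of 1.24 (SE 0.17) in young and 1.26 (SE 0.18) in old mice on the normal diet, and of 2.03 (SE 0.15) and 2.29 (SE 0.17) under restriction. The nuclear receptor gene Nr1d2 had 1.35 (SE 0.16) and 1.49 (SE 0.17) against 2.16 (SE 0.14) and 2.12 (SE 0.16), and the repressor gene Cry1 had 1.03 and 0.95 against 1.62 and 1.5. The test of a difference in rhythm between diets called Arntl, Cry1, Nr1d2 and Per2 in young mice (adjusted p from 0.00236 to 0.0252; 7 of 15 genes adjusted over the list alone). In old mice it called Arntl, Clock, Cry1, Nfil3, Nr1d2, Per2, Per3 and Tef (adjusted p from 0.00021 to 0.0244; 9 of 15 adjusted over the list alone).

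Clock genes peaked earlier under restriction. The hours at which the diets were given are not in the sources used here, so restriction and the time of feeding cannot be told apart. In old mice Arntl, the activator also called Bmal1, peaked 2.24 h earlier (SE 0.49), Clock 2.85 h (SE 0.73), Nfil3 3.43 h (SE 0.96) and Nr1d2 2.12 h (SE 0.50). The median peak of the 13 genes was moved by -1.87 h in old mice (permutation p = 0.00026, adjusted p = 0.0013) and by -0.78 h in young mice (permutation p = 0.0204, adjusted p = 0.0255). All 13 genes peaked earlier under restriction in old mice, and all but Per2 in young mice. With age the median peak was moved by 0.96 h on the normal diet (permutation p = 0.0481, adjusted p = 0.0481) and by -0.57 h under restriction (permutation p = 0.00693, adjusted p = 0.0115). By the curves fitted with sex, 10 of 13 genes peaked later with age on the normal diet, the exceptions being Cry2, Hlf and Per1, and 4 of 13 under restriction. These age shifts differed from each other by 1.54 h (permutation p = 0.00204, adjusted p = 0.0051). The adjusted values cover the 5 tests of this family, each two-sided with 100000 resamples of the age or diet labels within times of day. With 1 array left out, the later peak with age on the normal diet lay between 0.64 h and 1.28 h, the lowest without the old array ZT20 replicate 2.

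**Figure D3:**
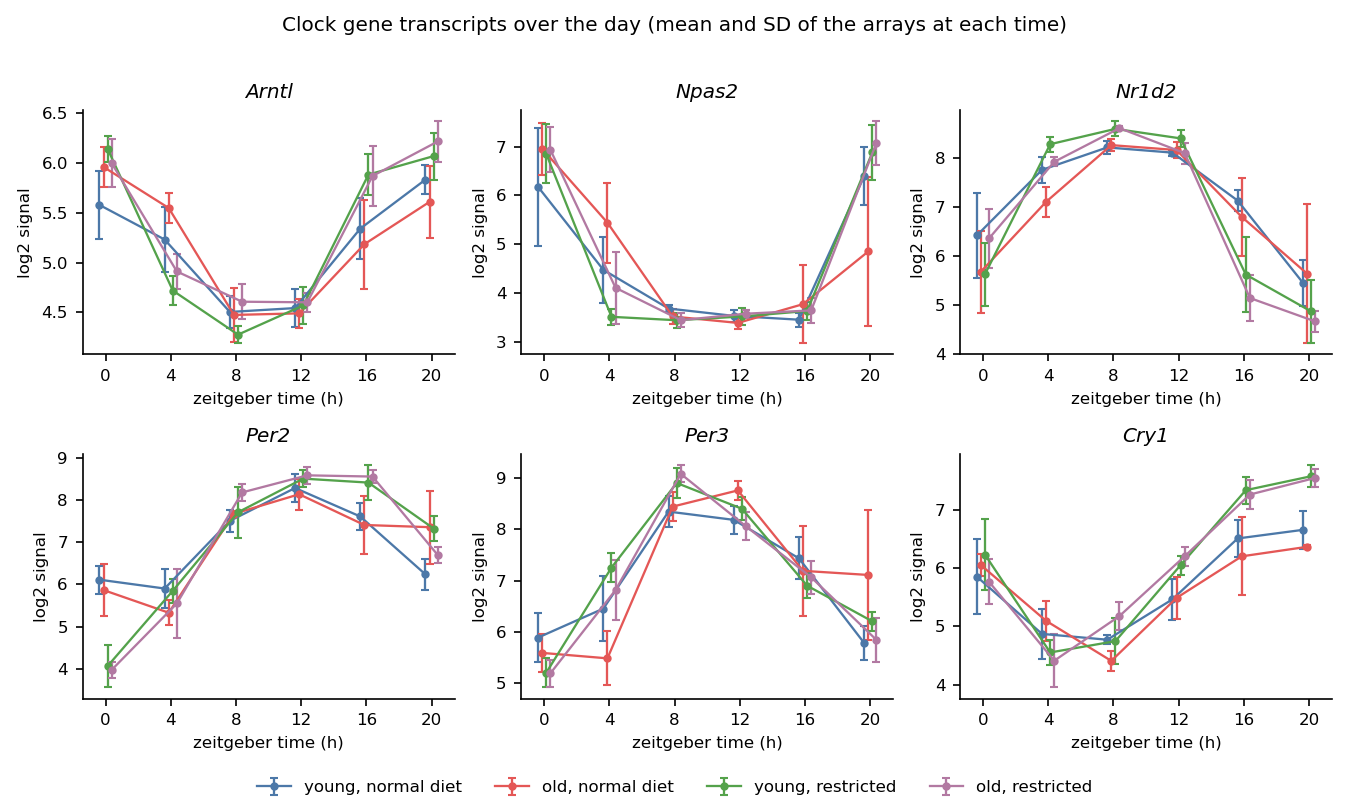
Log2 signal of 6 clock genes by zeitgeber time in hours, with points at the mean of the arrays of each age and diet group and bars for 1 SD (3 to 6 arrays). Both restricted groups swing more widely, as for Per2 with amplitudes of 2.03 and 2.29 against 1.24 and 1.26 on the normal diet.

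No single gene passed the cosine test of a difference in rhythm between old and young mice, on either diet, with all arrays. A fit of males alone rested at ZT16 on the outlying old male array, the only male of its group. In males alone 16 genes passed on the normal diet (1431 at an unadjusted p under 0.05). On the normal diet 0 genes passed limma's test on the cosine terms, with 628 at an unadjusted p under 0.05 where chance gives 589, and 2 genes passed the F test over the 6 times with no shape assumed (1240 at an unadjusted p under 0.05). Under restriction 0 genes passed the cosine test (544 at an unadjusted p under 0.05) and 1 passed the F test (1394). Adjusted over the list alone, 1 of 8 B and plasma cell genes passed for age on the normal diet. In simulated data of this design, 70% of genes with a 0.3 change in amplitude and 90% of genes of amplitude 0.6 with a peak moved by 3 h were called for age on the normal diet. The simulated noise was independent between genes, with equal spread in every group and no outlying array, so these shares may overstate recovery here. Smaller shifts, such as the median of 0.96 h seen for the clock genes, were not simulated.

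In contrast to age, diet went with a different daily profile, where restriction and the time of feeding cannot be told apart. The rhythm differed for 1163 genes in young and 1547 in old mice. These counts depended on the arrays used: they were 205 and 101 in females alone and 102 and 922 in males alone. Without the arrays of 1 replicate number they ran from 614 to 1105 and from 648 to 1534. Glucose-6-phosphatase (G6pc), which releases glucose from the liver, had an amplitude of 0.07 (SE 0.15) in young and 0.14 (SE 0.15) in old mice on the normal diet and of 1.08 (SE 0.13) and 1.40 (SE 0.16) under restriction. The change was a daytime trough (adjusted p = 0.000969 in young and 2.02e-05 in old mice). The mean signal of G6pc was 10.81 at ZT4 and 9.89 at ZT8 in young and 10.56 and 9.05 in old restricted mice. At the other times it lay between 12.05 and 12.26, and on the normal diet between 11.79 and 12.37 at all times. The cytosolic chaperone Hsp90aa1 had an amplitude of 0.48 and 0.36 on the normal diet and of 1.2 (SE 0.086) and 1.38 (SE 0.10) under restriction (adjusted p = 9.88e-08 and 2.28e-10). Acly, which makes cytosolic acetyl-CoA, changed its time of day. In old mice it peaked at ZT 6.21 on the normal diet and at ZT 19.7 under restriction (adjusted p = 5.42e-05), and in young mice at ZT 9.36 and 19.5 (adjusted p = 0.00595). Of the genes called, 951 in young and 1213 in old mice had a larger amplitude under restriction and 212 and 334 a smaller one. At both ages 698 were called, against 153 by independence. In young mice 608 of the genes called were rhythmic under restriction only and 88 on the normal diet only, and in old mice 777 and 201.

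Of 19 chaperones, 14 had a rhythm that differed by diet at each age (16 in young and 17 in old mice adjusted over the list alone). Only the neutrophil list in old mice had a larger share of its members, 3 of 3. The old normal-diet array ZT16 replicate 2 entered that comparison, with a neutrophil list mean of 9.59 where the next of its group had 6.19. The rhythm of this list was not tested without that array. Several chaperones of the endoplasmic reticulum changed their time of day. In young mice Hyou1 peaked at ZT 1.02 on the normal diet and at ZT 19.5 under restriction (adjusted p = 3.07e-06), Hspa5, the luminal HSP70, at 1.31 and 20.3 (adjusted p = 0.00029) and Manf at 1.37 and 20.7 (adjusted p = 0.00374). In old mice Creld2 had an amplitude of 0.33 (SE 0.14) on the normal diet and of 1.11 (SE 0.14) under restriction (adjusted p = 2.06e-05). Among the other genes with the largest differences, Hspa1b had an amplitude of 0.55 and 1.78 in young mice, the normal diet first (adjusted p = 0.0016), the small heat shock gene Hspb1 0.46 and 1.28 and the arrestin-like Arrdc3 0.41 and 1.57. In the same order, Slc41a2 had 0.33 and 1.41, the tubulin Tubb2a 0.41 and 1.40, Camk1d 0.61 and 1.1, Slc30a10 1.09 and 1.99, and the retinoic acid hydroxylase Cyp26b1 0.64 and 1.19. In old mice Cdkn1a had 0.67 and 1.84 (adjusted p = 0.0404) and Sphk2 1.88 and 2.45, with peaks at ZT 10.7 and 7.81 (adjusted p = 5.80e-06). Of 17 genes of cholesterol synthesis, 6 differed in young and 8 in old mice (9 and 11 adjusted over the list alone), among them Sc5d, with peaks at ZT 3.56 and 21.2 in young mice. Lipogenesis had 3 and 8 of 17 (4 and 10 adjusted over the list alone), the proteasome 7 and 10 of 31 (8 and 11) and acetyl-CoA metabolism 4 and 6 of 13 (5 and 6). With 3 arrays per time and group, 274 genes passed in young and 1028 in old mice, and in young mice the F test over the 6 times called 2438.

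**Figure D4:**
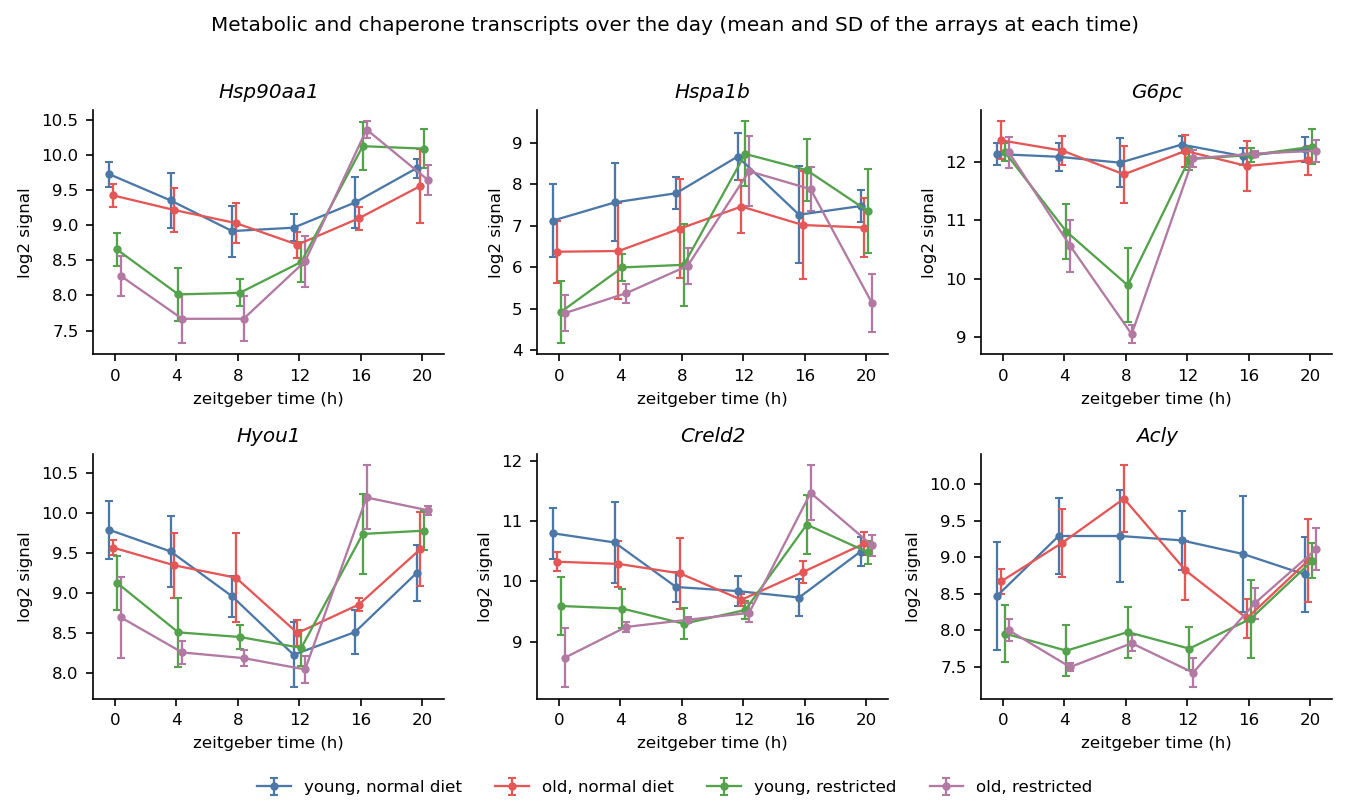
Log2 signal of 6 chaperone and metabolic genes by zeitgeber time in hours, with points at the mean of the arrays of each age and diet group and bars for 1 SD (3 to 6 arrays). G6pc is nearly flat on the normal diet (amplitudes 0.07 and 0.14) and under restriction falls to a trough at ZT8 (means of 9.89 in young and 9.05 in old mice), and Hyou1 moves its peak from ZT 1.02 to ZT 19.5 in young mice.

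Whether restriction moved genes against their change with age was examined across all genes. In old mice, 179 genes rose with age on the normal diet and fell under restriction, Clec7a, C1qa and H2-Eb1 among them, where independent lists would share 69.8. A further 65 fell with age and rose under restriction, Cd163 among them, against 55.6. In both comparisons 12 rose (53.0 by independence) and 100 fell (73.2), Ociad2 and Mogat1 among them. The old normal-diet arrays entered both comparisons, with opposite signs. Their noise alone therefore favours calls in opposite directions over calls in the same direction. The counts by independence leave this out, so they do not show an excess beyond chance here. The correlation across genes, which are not independent replicates, was r = -0.15, and unchanged groups that share arrays gave -0.528 in simulations. The covariance of -0.00368 exceeded the simulated -0.0019 in size, by a difference of -0.00178. With the shared arrays split between the comparisons r was -0.0505 and the covariance -0.000905. With the diet effect in young mice, age on the normal diet had r = 0.0694 (simulated 0.511) and a covariance of 0.00165 against a simulated 0.00165. With the shared young arrays split r was -0.0149 and the covariance -0.000409. In young mice 114 genes rose with age and fell under restriction (67.7 by independence), 154 fell in both (71.0), 33 rose in both (59.1) and 24 fell with age and rose under restriction (61.9). Here the young normal-diet arrays entered both comparisons with the same sign, which favours calls in the same direction. The counts by independence leave this out as well. Without the 4 young arrays with outlying sex-linked transcripts r was -0.0816 for old mice, and without the 2 arrays with the highest neutrophil values it was -0.0857.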

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

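The tests and simulations of single genes for the sex difference without the old male array, of wrong sex labels and of an adjustment with the other sex, and the counts over regrouped arrays, were chosen only after the result was seen.

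A measure of the gap between an array and the rest of its group was applied to 7 measures in the 21 groups of 4 to 6 arrays, 147 tests in all, and 7 values from 6 arrays stood out, about as many as the 1 in 20 that chance gives. The old male array on the normal diet at ZT16 (replicate 2) stood out with an acute phase list mean of 11.36 (next array 10.25) and a neutrophil list mean of 9.59 (next array 6.19). The macrophage list mean was 8.27 in the old normal-diet array ZT12 replicate 4 (next 7.58) and 8.18 in the young restricted array ZT0 replicate 4 (next 7.65). Among sex-linked transcripts, Xist was 5.78 in the old restricted array ZT12 replicate 5 (next 4.37), Eif2s3y 13.09 in the young normal-diet array ZT12 replicate 1 (next 9.87) and Kdm5d 6.61 in the young restricted array ZT0 replicate 5 (next 6.91).

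The effect of age on the normal diet differed between males and females for 158 genes, 78.5% of them with the larger value in males, led by macrophage genes: Cxcl13 rose by 1.91 in males (SE 0.28) with -0.33 in females (SE 0.32; difference adjusted p = 0.0181), and Ms4a7 by 1.15 (SE 0.15) with -0.30 (SE 0.18; 0.00399). The old male array ZT16 replicate 2 was the only male of its group, so the values in males alone rested on it at ZT16. Without it, limma called 0 genes (1004 at an unadjusted p under 0.05), because the differences shrank while their errors stayed. The difference went from 2.14 (SE 0.484) to 1.66 (SE 0.48; adjusted p = 0.276) for Cxcl13 and from 1.37 (SE 0.255) to 1.14 (SE 0.254; adjusted p = 0.15) for Ms4a7. The 158 genes kept a median share of 0.753 of their difference, where any other normal-diet array left out gave 0.928 to 1.16, so the array enlarged the differences more than any other. For these genes the share kept cannot tell the array as the whole source from a wider difference, since they were picked with the array included. In 100 simulations only the array differed: 10 called any gene and 1 called as many as in the data. The genes called in them kept a median share of 0.744 to 1.01, a range that holds the 0.753. The array alone thus seldom gave so many genes, but the share kept does not decide. Leaving out another old normal-diet array gave 26 to 585 genes and a young one 34 to 340. The mean of the macrophage list still rose more in males without the old male array, by 0.76 on the log2 scale (permutation p = 0.00792), against 0.97 with it (permutation p = 0.00113). This list was chosen because macrophage genes led the difference with the array included, and it holds called genes such as Marco. The test is therefore no independent support, and whether a difference remains that does not need the array is open. Of 100 groupings with exchanged sex labels, 2 gave as many genes, the real one with 158 and another with 239. Chance is not excluded, since a random exchange gave more genes than the real labels and the comparison was chosen after the count was seen. Why that exchange gave more was not tested. The age effect under restriction and the diet effects in young and old mice had 0 genes that differed by sex (689, 509 and 1591 at an unadjusted p under 0.05); with a count of 0 the 100 groupings cannot test this.

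In 4 young normal-diet arrays, picked after their values were seen, sex-linked transcripts lay far from the other arrays: Eif2s3y at 13.09 and 10.82 in the males ZT12 replicate 1 and ZT20 replicate 4, and Xist at 6.47 and 6.56 in the females ZT12 replicate 2 and ZT20 replicate 3. Wrong sex labels would have lowered these transcripts if the values were adjusted by the label, but no source used here records an adjustment. The lower Eif2s3y of the males lay 1.62 above the median of the other males (SD 0.28). The lower Xist of the females lay 2.17 above that of the other females (SD 0.51). The arrays were picked for these high values, so the values are no test of the labels, and wrong labels stay open. The score of the sex-biased gene lists cannot tell an adjustment with the other sex from ordinary spread. By it 37 other arrays lay as far to the side of their sex label as at least 1 of the 4, which had 3, 6, 10 and 27 such arrays each. The sex-linked values above lay beyond that spread, but the reciprocal ones moved little. Eif2s3y of the 2 females lay 0.35 and 0.36 above the median of the other females (SD 0.33), not below it. Xist of the 2 males was 3.66 and 4.10, against a median of 4.28 in the other males (SD 0.31). Whether these arrays were adjusted with the other sex thus stays open. The deviations of the pair of males correlated at 0.341 across 11451 genes outside the sex lists, above the 95th percentile of other pairs (0.237), and those of the females at 0.278, which is consistent with an adjustment that also moved other genes. No biological explanation was tested.

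The test of whether the effect of diet differed with age called Gm10037 (interaction -0.257, SE 0.049, adjusted p = 0.0126) and Syce2 (0.237, SE 0.048, adjusted p = 0.0198), both with the same sign at 6 of 6 times of day. Chance cannot be excluded for them, since 6 of 100 groupings of the arrays gave as many genes, the highest other 327. Without the 4 young arrays limma called 0 (785 at an unadjusted p under 0.05). Among 5392 probe sets without a single gene name, which the report does not use, 96 passed for age on the normal diet, 231 for age under restriction, 1622 for diet in young mice and 1642 for diet in old mice.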

How the results depend on the processing

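The runs without the 4 young arrays with outlying sex-linked transcripts and without the 2 arrays with the highest neutrophil values were chosen only after the result was seen; the other alternatives were fixed before the data were examined. No direction of a gene named for level turned: of 2024 values under the alternatives, 1817 kept their side of the threshold and 207 lost it. Of 1966 values for rhythm 1939 kept their side, and of 440 for differences in rhythm 411 did. For rhythm only the side of the threshold was compared, so a turn in peak time or amplitude change would not have been seen. Quantile normalization, median centring, the mean of a gene's probe sets, a model without sex, and leaving out the arrays with contradictory ages left every count of genes within 1.5 times, but the share of higher genes moved: with each array centred on its median it was 30.1% and 24.5% for age (normal and restricted diet) and 54.4% and 52.9% for diet (young, old), and after quantile normalization 50.3%, 45.2%, 57.3% and 57.3%. The cause was not tested for any value below, except that runs with fewer arrays or 1 sex hold fewer samples. With males alone, the outlying array ZT16 replicate 2 was the only old normal-diet array at its time. The counts in males alone therefore rest on it there and do not show a difference between the sexes.

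In females alone 12 genes passed for age on the normal diet, 311 for age under restriction, 2036 for diet in old mice and 0 for the interaction (limma; 891 at an unadjusted p under 0.05); rhythmic genes numbered 1203, 404, 3652 and 2520 (young and old on the normal diet, young and old restricted), genes whose rhythm differed by diet 205 in young and 101 in old mice, and lists called for age under restriction 8. In males alone the counts were 1721 for age on the normal diet, 3 for age under restriction, 2531 for diet in young mice, 513 for the interaction, 16 for age on rhythm on the normal diet, 102 and 922 for diet on rhythm in young and old mice, 802, 3131 and 3102 rhythmic genes (young normal diet, young and old restricted) and 15 lists for the interaction. In females the interaction turned for cholesterol synthesis (adjusted p = 0.0744), PPAR-alpha targets (0.669) and oxidative phosphorylation (0.257), and in males oxidative phosphorylation turned for age under restriction (0.388).

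Without the old array ZT16 replicate 2, which stood apart, 204 genes passed for age on the normal diet, 201 of them among the 594; with only the groups compared, 174 passed (167 among the 594). Without the 4 young arrays, 157 passed for age on the normal diet (148 among the 594), 0 for the interaction (785 at an unadjusted p under 0.05) and 3 lists for the interaction. Without the 2 arrays with the highest neutrophil values, 249 passed for age on the normal diet (246 among the 594), 5 lists for the interaction, and 0 genes for the sex difference in the age effect (1033 at an unadjusted p under 0.05). The interaction had 1 gene with the dimmer genes left out up to the median and 4 with array weights.

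The rank test called 2420 rhythmic genes in young and 1464 in old mice on the normal diet. With 3 arrays per time 2506, 2774, 3635 and 4351 were rhythmic (young and old on the normal diet, young and old restricted), and the rhythm differed by diet for 274 genes in young and 1028 in old mice. The F test over the 6 times called 2 and 1 genes for age on rhythm (normal and restricted diet) and 2438 for diet in young mice. With an estimated correlation camera called 0 lists for age on the normal diet, 0 for age under restriction, 2 for diet in young mice, 2 in old mice and 0 for the interaction; fry called 1 for age under restriction, 22 and 27 for diet in young and old mice and 0 for the interaction.

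The correlation of the age effect on the normal diet with the diet effect in old mice was -0.0505 with the shared arrays split, -0.175 with no filter, -0.105 with the dimmer genes left out up to the median, -0.0816 without the 4 arrays and -0.0857 without the 2. With the diet effect in young mice it was -0.0149 (turned) with the shared arrays split, 0.103 with the dimmer genes left out up to the median, 0.11 without the 4 and 0.12 without the 2, and with the age effect under restriction 0.61 and 0.503 without the 4 and the 2.

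With 1 array or 1 replicate number left out in turn, counts ran from 54 to 854 for age on the normal diet, 43 to 1259 for age under restriction, 4180 to 5262 and 3696 to 5136 for diet in young and old mice, and 0 to 6 for the interaction. Rhythmic genes ran from 2218 to 3731 and 1614 to 3644 on the normal diet and from 4947 to 5781 and 3994 to 5198 under restriction (young, old), age on rhythm stayed at 0, and diet on rhythm ran from 614 to 1258 and 648 to 1672. With 1 replicate number left out, lists called ran from 11 to 15, 11 to 15, 9 to 13, 11 to 17 and 5 to 8 in the order of the comparisons of level.

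With the replicate number as a term (replicate block), 519 genes passed for age on the normal diet, 609 for age under restriction, 4838 and 4880 for diet and 2 for the interaction, 3484, 3417, 5644 and 4990 were rhythmic, 0 and 0 differed in rhythm by age and 1090 and 1478 by diet, and 12, 14, 10, 12 and 7 lists were called, so the replicate block moved no count by over 1.5 times. With the replicate block Mmp9 (adjusted p = 0.0584) and Sult2a8 (0.0554) missed the threshold for age on the normal diet, and Pf4 (0.0728) and Ms4a6d (0.103) for age under restriction. Arrays of the same replicate number in different groups did not deviate together (median correlation -0.0157 over 1067 pairs, against 0.00552 over 4009 pairs of other numbers), so the numbers do not pair the arrays.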

Other observations

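The counts over regrouped arrays and the tests of whether the age shift of the clock differed between diets or was removed by restriction were chosen only after the result was seen. Several fixed lists that camera did not call held single genes with large diet effects. In the growth hormone and IGF axis, 6 of 10 genes rose and 3 fell in young mice (6 and 4 adjusted over the list alone) and 3 rose and 3 fell in old mice (4 and 3 adjusted over the list alone): Igfbp2 and Socs2 rose, as did Igfals, by 0.44 and 0.24 on the log2 scale, while Igfbp1 fell by 0.37 and 0.76 and the receptor gene Ghr by 0.26 and 0.25 (camera adjusted p = 0.158 and 0.61). In the gluconeogenesis and fasting list, Pck1 was the only one of 10 genes that rose, and 4 fell at both ages (the same adjusted over the list alone), the hormone gene Fgf21 by 0.43 and 0.36 and Lpin1 by 0.49 and 0.54 (0.596 and 0.316). Among bile acid genes, Cyp8b1, the sterol 12-hydroxylase, fell by 0.70 and 0.59, with 3 of 16 higher and 3 lower in young and 4 and 6 in old mice (0.965 and 0.904). Of 9 genes of NAD metabolism and sirtuins, 3 rose and 4 fell in young mice (4 and 4 adjusted over the list alone) and 2 and 4 in old mice, among them Nnmt, which methylates nicotinamide and rose by 0.63 and 0.38, and the desuccinylase Sirt5, which fell by 0.74 and 0.48 (0.695 and 0.563). Of 9 female-biased genes, 4 rose in young and 5 in old mice, the transporter gene Slc22a26 most, and Cyp17a1 fell by 1.19 and 1.49 (0.211 and 0.0851). The autophagy kinases Ulk1 and Ulk2 fell by 0.27 and 0.46 in young mice and by 0.35 and 0.55 in old mice, within a list of 14 in which 1 rose and 5 or 6 fell (0.306 and 0.253), and the mean level of chaperones was lower for 9 of 19 genes in young and 10 in old mice, with Hspa8 lower by -0.52 and -0.52 (0.0729 and 0.071).

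The remaining lists were not called for diet by camera either, although fry called some of them. For the mean level of the clock genes under restriction, 4 of 15 rose and 1 fell in young mice and 6 rose and 1 fell in old mice (7 and 1 adjusted over the list alone), with rises of 0.40 and 0.46 for Cry1 and decreases of 0.48 and 0.58 for Bhlhe40 (camera adjusted p = 0.335 and 0.159). Cholesterol synthesis had 7 higher and 3 lower of 17 in young mice and 4 and 4 in old mice (0.198 and 0.956), NRF2 targets 2 and 3 of 10 and then 4 and 1 (0.805 and 0.256), PPAR-alpha targets 1 and 8 of 19 and then 4 and 5 (0.122 and 0.956), acute phase 2 and 5 of 14 and then 2 and 6 (0.198 and 0.374), the cell cycle 5 and 4 lower of 10 (0.0729 and 0.267) and the proteasome 4 higher of 31 at each age with 11 and 9 lower (0.198 and 0.226). Endothelial markers had 3 higher and 1 lower of 12 in young and 6 and 0 in old mice (0.405 and 0.155), B and plasma cells 3 and 4 lower of 8 (0.126 and 0.377), cholangiocytes 0 and 2 higher of 6 (0.509 and 0.316), exocrine pancreas 2 higher and 1 lower of 9 and then 1 lower (0.534 and 0.898), adipocytes 1 and 0 lower of 3 (0.534 and 0.723), hepatocytes 3 and 4 higher of 7 (0.141 and 0.0501) and neutrophils 0 of 3 at either age (0.805 and 0.723). With age, 1 of 17 lipogenesis genes fell on the normal diet (Me1; camera adjusted p = 0.0599), Ass1 of 8 urea cycle genes rose (0.0966), Sesn2 of 10 p53 targets fell (0.473), Dcn of 11 stellate genes rose (0.0599) and Dnajb1 and Hspa1b of 19 chaperones fell (0.536). The median and mean of a list differed in sign for chaperones with age on the normal diet (0.00266 and -0.049), and for PPAR-alpha targets (0.00691 and -0.10) and cholesterol synthesis (0.03 and -0.06) under restriction in old mice, among others near 0. In old mice all 3 neutrophil genes had a rhythm that differed by diet (S100a9 amplitude 0.96 on the normal diet, with a peak at ZT 16.0, and 0.096 under restriction; adjusted p = 0.012), and the old male array with the highest neutrophil values was taken at ZT16.

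In old mice on the normal diet the median peak of 13 clock genes was 0.96 h later than in young mice, with a permutation p of 0.0481, just inside the threshold. By the curves fitted with sex, 10 of the 13 peaked later, and Cry2 (-0.61 h), Hlf (-0.89 h) and Per1 (-1.03 h) did not. The shift was at least 0.639 h with any 1 of the 47 arrays left out, which argues against a single array as its whole source. It was 0.859 h without the 4 young arrays with outlying sex-linked transcripts, which argues against those as its whole source. The permutation test was not repeated without any of these arrays, so whether the shift would still pass the threshold is open. The shift was 0.87 h in females and 1.15 h in males. A later clock with age that restriction merely removes would leave no shift, and the shift of -0.57 h under restriction (permutation p = 0.00693) argues against it. A candidate explanation is an effect of age on the clock that depends on diet, since the shifts differed by 1.54 h (permutation p = 0.00204). The hours at which the diets were given are not in the sources used here, so a shift by the time of feeding stays open and untested. The pattern was found and tested on the same arrays.

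Counts were compared with those of 100 groupings of the arrays, the real one included. For age on the normal diet (594, highest other 9) and age under restriction (911, highest other 7), only the real grouping gave as many genes. So it was for diet in young mice (5152, highest other 196) and diet in old mice (4993, highest other 723). The same held for rhythmic genes (3696, 3450, 5806 and 5098, highest others 510, 518, 1466 and 1367) and for diet on rhythm (1163 and 1547, highest others 62 and 199). These counts lay above those of every exchange tried. A share of 1 of 100 is the smallest that 100 groupings can give, and it was not adjusted over the comparisons, so chance is not strictly excluded. Chance cannot be excluded for the 2 genes of the interaction, where 6 groupings gave as many and the highest gave 327. The source of that number was not tested. For age on rhythm the real count was 0 on both diets, so that all 100 groupings give as many by definition and the comparison says nothing about chance. For age under restriction camera called 14 lists, and 2 groupings gave as many, the real one and another with 14. That share was not adjusted over the comparisons, so chance is not excluded for this number of lists. Nor can it be for age on the normal diet (12 lists, 13 groupings, highest other 17) and the interaction (8, 39 groupings, 17). The same holds for diet in young mice (10, 11 groupings, 16) and in old mice (12, 23 groupings, 18). The median of the other groupings was 7, 5, 5, 8 and 6 lists for age on the normal diet, age under restriction, diet in young mice, diet in old mice and the interaction.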
